A study of Homo sapiens with 12 samples.

How the data were processed

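RNA was measured in 12 libraries of the human mesothelioma cell line NCI-H226, NF2-null per the labels, and of its derivative NCI-H226_CL3, which per the labels' protocols was made resistant by growth in rising concentrations of a TEAD inhibitor from 0.25 to 3 µM. The tissue label names lung epithelium and the cell type label mesothelioma, which is followed here, so that the marker lists do not settle the origin of the cells. Each line was incubated with vehicle (DMSO) or with the TEAD inhibitor GNE-7883, giving 4 groups of 3 libraries. The dose and the duration of that final incubation are not given in the sources used here. Libraries were made from total RNA with the TruSeq RNA kit v2, which does not mark strand, and sequenced as single-end 50-base reads, on average 56 M reads per sample per the labels. The submitters' processing notes name the aligner GSNAP, the genome build GRCh38.p10 and limma, without saying which step each served. The counting tool, the annotation release and the strand setting are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and counts of near-identical copies (SAA1 and SAA2, the keratin-associated protein genes, the AKR1C genes, the surfactant protein A genes) are uncertain.

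The authors deposited a count table, whole-number read counts per Ensembl gene with no normalization, with 58302 genes and 1 column per library. The authors deposited a second table of RPKM values for the same genes and libraries. Over 12122 genes with at least 50 counts, the ratio of count to RPKM was checked to be the product of a gene factor and a library factor, and the library factors equalled the totals of the count table within a relative deviation of 1.2e-08. Total counts ran from 31878934 to 46962645 per library, so that 3 counts, the upper limit that a count of 0 allows, correspond to 0.0639 CPM in the deepest and 0.0941 CPM in the shallowest library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Of the genes, 22952 had a count of 0 in all 12 libraries. Symbols came from a table of gene names, and coordinates, biotypes, GC content and transcript length from GENCODE release 29 on GRCh38, which may differ from the annotation the authors counted with; 58039 identifiers matched and the 263 others held at most 0.0167% of a library's counts.

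Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter with the group as factor (18035 genes kept), quasi-likelihood fits with 1 mean per group over all 12 libraries (8 residual degrees of freedom), two-sided tests, and Benjamini-Hochberg adjustment within each of 5 comparisons. A gene is called, and described as having risen or fallen, at an adjusted p under 0.05 in that test. The comparisons were GNE-7883 against DMSO in sensitive cells, the same in resistant cells, resistant against sensitive cells in DMSO, the same in GNE-7883, and the difference of the GNE-7883 responses (resistant minus sensitive). The error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic, and group levels are means of TMM-scaled CPM with SD, n = 3. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Only 1 resistant line was profiled, so a difference between the lines is a difference between these cultures.

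The comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined. The 31 lists were YAP/TEAD targets (22 genes), Hippo pathway components, MAPK pathway activity genes (10 genes), other ERK feedback and output genes, AP-1 and other immediate early genes, receptor tyrosine kinases, growth factor ligands, RAS-MAPK components, S-phase and G1/S genes, G2/M and mitosis genes, CDK inhibitors and D cyclins, BCL-2 family genes, mesothelial, epithelial, mesenchymal and squamous markers, cytoskeletal SRF/MRTF targets, alveolar and airway, blood and endothelial markers, cholesterol synthesis genes, fatty acid synthesis genes, ATF4 integrated stress response genes, interferon-stimulated genes, NF-kB cytokine genes, TGF-beta response genes, p53 targets, NRF2 targets, drug efflux and metabolism genes, hypoxia and glycolysis genes, and Wnt and Notch targets. Some genes stand in more than 1 list. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, which compares a list with all other genes, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks only whether a list's genes move, on balance, 1 way. Named genes are, per comparison, the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with at least 5 CPM in a group compared and, in comparisons of 2 groups, no overlap between their libraries (clones, pseudogenes and antisense names left out), up to 4 called members of each list with the smallest p-values, and 24 genes of the Hippo and MAPK pathways named whatever their values. Results of some genes that this rule names are not reported here.

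The scripts were tested on simulated counts drawn with the means of the sensitive DMSO group and the estimated dispersions and library sizes of the real data, with 200 genes changed in 1 group. For GNE-7883 in sensitive cells the test recovered 14% of 50 genes changed 1.2-fold, 80% of those changed 1.5-fold and 98% of those changed 2-fold, and for the same comparison in resistant cells 12%, 90% and 98%. For resistant against sensitive cells in DMSO the shares were 20%, 74% and 96%, in GNE-7883 12%, 90% and 96%, and for the difference of responses 2%, 76% and 90%. In the real comparisons 9.2% to 61.9% of genes were called, a far larger share than was changed here. The Benjamini-Hochberg threshold loosens as more genes change, so these shares do not give the recovery of small changes in the real data. Of 40 random lists in simulated data camera called 0, with the preset and with the estimated correlation. The simulated genes were drawn independently, so this does not test the preset correlation on genes that move together. Alternatives tried were DESeq2 size factors, library size alone, no low-count filter, a filter of 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test without the low-count filter (genes with any count), limma-voom, limma-trend on log2 of the deposited RPKM plus 0.1 or plus 1, fits on 2 groups, the replicate number as a block, a test against a 1.5-fold change (glmTreat), and leaving out each library. Replicate numbers did not pair the libraries across groups: over 18 pairs of equally numbered libraries, correlations of their deviations from the group mean ran from -0.119 to 0.18. A correction of each library for GC content and transcript length (natural splines, 5 degrees of freedom), alone and with the block, was added after seeing the data. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.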

Results

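Gene expression was measured by RNA sequencing in NCI-H226 cells, a human mesothelioma line that the labels call NF2-null and sensitive to GNE-7883, and in NCI-H226_CL3, a line derived from it by growth in rising concentrations of a TEAD inhibitor. GNE-7883 inhibits TEAD, the DNA-binding partner of YAP and TAZ at the end of the Hippo pathway. Each line was incubated with DMSO or GNE-7883, for a time and at a dose that the labels do not give, with 3 libraries in each of the 4 groups. Total counts were 44744884, 42822017 and 37728690 in sensitive DMSO replicates 1 to 3, and 36953126, 34035917 and 38708770 in sensitive GNE-7883. They were 42326002, 45178434 and 31878934 in resistant DMSO replicates 1 to 3, and 46962645, 41670003 and 35737227 in resistant GNE-7883. The series concerns acquired resistance to TEAD inhibition and the joint action of the Hippo and MAPK pathways, so genes of both pathways are given in each comparison.

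The libraries grouped by line and treatment. The first principal component held 65.9% of the variance and parted the lines, and the second held 17.6%. On the first component the sensitive groups lay at -23.8 to -22.2 (DMSO) and -85.1 to -83.1 (GNE-7883), and the resistant groups at 60.1 to 63.4 (DMSO) and 45 to 45.8 (GNE-7883). Sensitive DMSO replicate 2 stood apart from replicates 1 and 3 of its group: the chi-square per degree of freedom between counts was 39.96 and 45.93 against 3.35 between the other two, and 3.53 to 11.44 within the other groups. Its deviations from the group mean followed GC content (Spearman rho 0.54 across genes) and transcript length (rho -0.67 across genes). In libraries of the other groups rho ran from -0.7 to 0.74 for GC content and from -0.24 to 0.38 for length. A rank correlation with GC content of that strength was therefore not particular to it, though its correlation with length lay beyond the range of the other groups. Rank correlations do not give the size of a trend. The SD of its log2 deviations was 0.187, against 0.0521 to 0.0962 in libraries of the other groups. Mitochondrial transcripts took 0.556 ± 0.0569% of counts in sensitive DMSO, 1.007 ± 0.0734% in sensitive GNE-7883, 0.604 ± 0.0699% in resistant DMSO and 0.657 ± 0.0399% in resistant GNE-7883 cells (SD, n = 3). NF2, the upstream Hippo gene, had 15 counts over the 12 libraries, at 5, 3, 2 and 5 in these groups, and was too low to test.

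The comparison of GNE-7883 with DMSO in sensitive cells asks what TEAD inhibition does to these cells. YAP/TEAD target genes fell. CCN2, a secreted matricellular protein and a classical YAP target (ENSG00000118523, chromosome 6, 131948176 to 131951373 on GRCh38), went from 64.3 ± 0.934 to 8.49 ± 0.299 CPM (SD, n = 3), a log2 fold change of -2.92 ± 0.061 (standard error, adjusted p = 1.63e-14, edgeR quasi-likelihood test, Benjamini-Hochberg). Values given after gene symbols are log2 fold changes with their standard errors, for 3 libraries per group. CCN1, its relative (ENSG00000142871, chromosome 1, 85580761 to 85583962), went from 1013 ± 32.8 to 409 ± 11 CPM, and the cardiac ankyrin repeat gene ANKRD1 fell by 2.60 on the log2 scale. NPPB, which encodes a natriuretic peptide (ENSG00000120937, chromosome 1, 11857464 to 11858931), fell most among the genes named in this comparison, from 107 ± 11.6 to 5.67 ± 0.534 CPM (-4.23 ± 0.11). Of the YAP/TEAD targets 2 rose and 17 fell of 22 tested (2 and 17 adjusted over the list alone). Their median was -0.76 on the log2 scale (camera adjusted p = 3.45e-07, adjusted p = 0.0422 with an estimated correlation, 7.51e-09 to 0.0422 over its alternatives). Coagulation factor F3 (-2.81 ± 0.057), IGFBP3 (-2.48 ± 0.052), CCDC80 (-1.59 ± 0.044), the receptor kinase AXL (-0.99 ± 0.051) and AMOTL2 (-0.73 ± 0.068) also fell. THBS1 (-3.48 ± 0.12), KRT4 (-3.45 ± 0.096), FGF1 (-3.38 ± 0.14), MGLL (-3.31 ± 0.074) and ANKRD2 (-3.24 ± 0.13), outside that list, were among the genes of at least 5 CPM in a group that fell most. Among Hippo pathway components 9 rose and 9 fell of 26 tested (10 and 9 adjusted over the list alone). Their median was -0.04 on the log2 scale (camera adjusted p = 0.942). TEAD4 (-1 ± 0.071), LATS2 (-0.79 ± 0.072) and TEAD3 (-0.38 ± 0.065) fell, while WWTR1, which encodes TAZ (0.82 ± 0.076), AMOT (1.61 ± 0.17) and YAP1 (0.48 ± 0.086) rose.

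**Figure D1:**
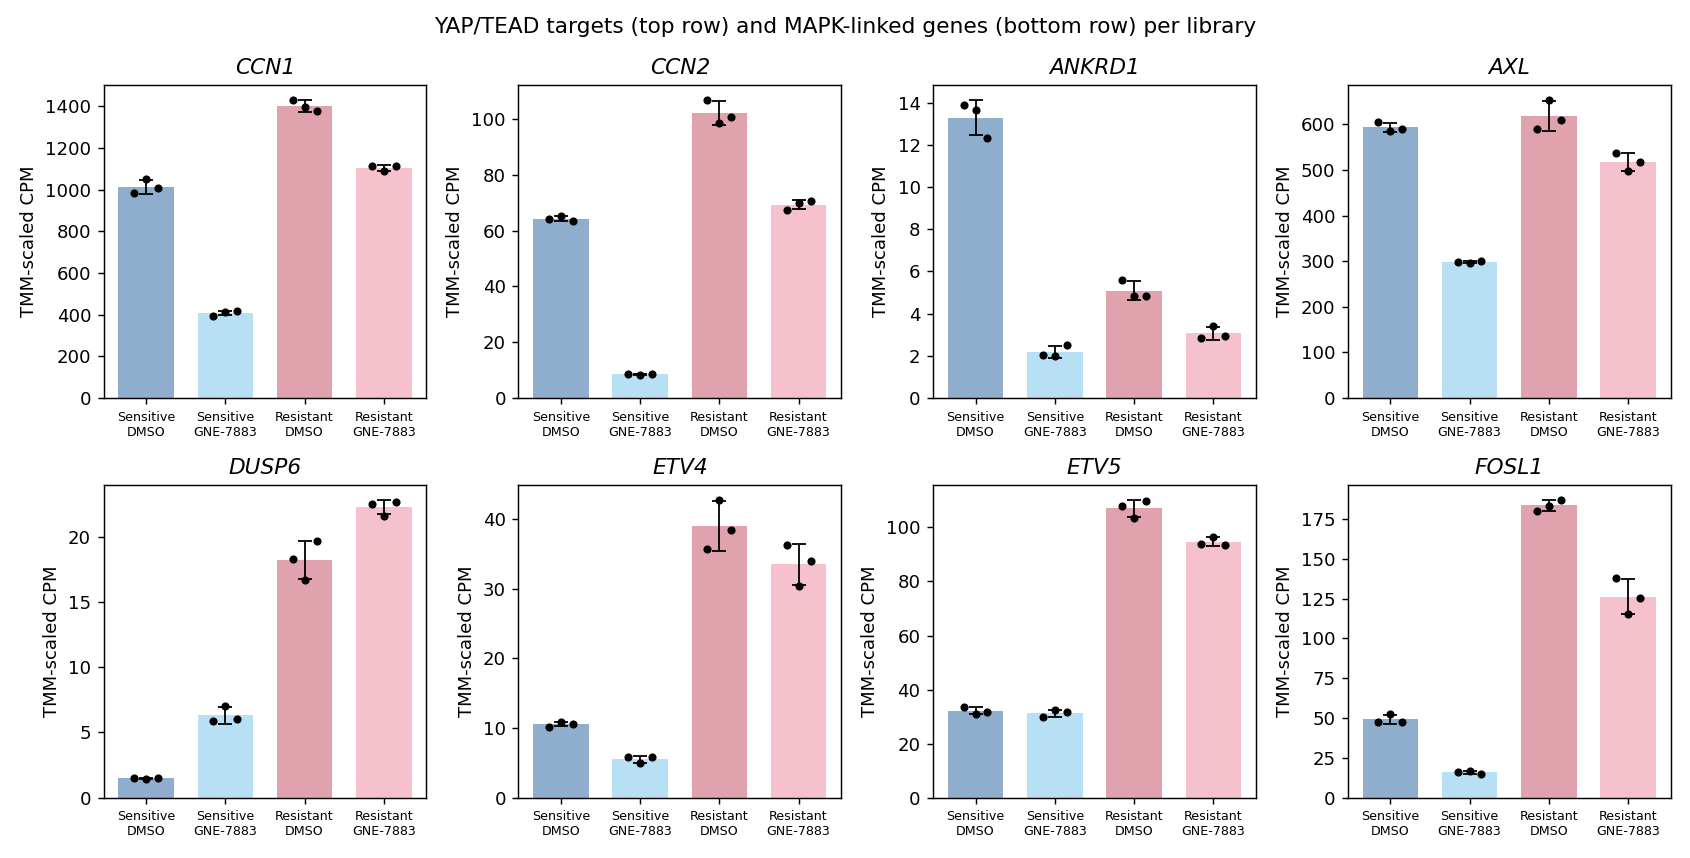
Level of 4 YAP/TEAD target genes (CCN1, CCN2, ANKRD1, AXL) and 4 MAPK output genes (DUSP6, ETV4, ETV5, FOSL1) in the 4 groups, as TMM-scaled CPM, with bars for the mean, error bars for the SD and points for the 3 libraries. CCN2 lies at 8.49 ± 0.299 CPM in sensitive cells with GNE-7883 and at 69.3 ± 1.61 CPM in resistant cells with it.

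Cell cycle genes fell in sensitive cells with GNE-7883, while interferon and cytokine genes rose, in libraries whose mitochondrial share was also higher. Among S-phase genes 0 rose and 25 fell of 26 tested (0 and 25 adjusted over the list alone). Their median was -1.03 on the log2 scale (camera adjusted p = 2.23e-14, adjusted p = 0.00242 with an estimated correlation, 4.39e-15 to 0.00242 over its alternatives), with the replication genes CDC6 (-1.53 ± 0.056), GINS2 (-1.78 ± 0.068) and MCM2 (-1.32 ± 0.061) as examples. Among G2/M genes 0 rose and 26 fell of 26 tested (0 and 26 adjusted over the list alone). Their median was -1.21 on the log2 scale (camera adjusted p = 1.05e-17, adjusted p = 0.0221 with an estimated correlation, 1.17e-19 to 0.0221 over its alternatives), with the mitotic cyclins CCNA2 (-1.55 ± 0.053) and CCNB1 (-1.53 ± 0.057). Of CDK inhibitors and D cyclins 5 rose and 6 fell of 14 tested (5 and 7 adjusted over the list alone). Their median was -0.05 on the log2 scale (camera adjusted p = 0.952). The CDK4/6 inhibitor gene CDKN2B rose (1.59 ± 0.057) and CCND1 fell (-0.62 ± 0.063). Among genes of at least 5 CPM in a group, the largest rises were in HP, which encodes haptoglobin (ENSG00000257017, chromosome 16, 72054592 to 72061055), from 2.07 ± 0.651 to 81 ± 8.51 CPM (5.27 ± 0.15), in PRG4, which encodes the lubricant lubricin (4.59 ± 0.12), MAP1A (4.09 ± 0.2), MXRA5 (3.77 ± 0.17) and the mucin MUC16 (3.75 ± 0.37). The ubiquitin ligase gene FBXO32 rose from 27.1 ± 1.95 to 289 ± 8.41 CPM (3.42 ± 0.064). Of mesothelial markers 11 rose and 3 fell of 14 tested (11 and 3 adjusted over the list alone). Their median was 0.45 on the log2 scale (camera adjusted p = 0.0296, adjusted p = 0.256 with an estimated correlation, 0.0108 to 0.256 over its alternatives), HP among them. Of epithelial markers 1 rose and 6 fell of 10 tested (1 and 6 adjusted over the list alone). Their median was -0.93 on the log2 scale (camera adjusted p = 0.041, adjusted p = 0.174 with an estimated correlation, 0.0304 to 0.207 over its alternatives, and 0.207 with a filter of 5 CPM), with CDH1 at -2.63 ± 0.24.

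Of interferon-stimulated genes 25 rose and 0 fell of 27 tested (25 and 0 adjusted over the list alone). Their median was 1.26 on the log2 scale (camera adjusted p = 3.23e-10, adjusted p = 0.256 with an estimated correlation, 7.33e-13 to 0.256 over its alternatives), among them CMPK2 (1.80 ± 0.1), IFIT1 (1.72 ± 0.11) and STAT2 (0.91 ± 0.063). Of NF-kB cytokine genes 18 rose and 1 fell of 21 tested (19 and 1 adjusted over the list alone). Their median was 0.84 on the log2 scale (camera adjusted p = 1.26e-06, adjusted p = 0.174 with an estimated correlation, 1.58e-07 to 0.174 over its alternatives), among them the chemokine CCL2 (1.90 ± 0.068) and the NF-kB inhibitors TNFAIP3 (1.64 ± 0.066) and NFKBIA (1.28 ± 0.058). Of NRF2 targets 10 rose and 3 fell of 18 tested (10 and 3 adjusted over the list alone). Their median was 0.42 on the log2 scale, with the efflux pump ABCC3 at 2.34 ± 0.069. That list was called (camera adjusted p = 0.0326, adjusted p = 0.256 with an estimated correlation, 0.0255 to 0.256 over its alternatives), but not with a filter of 5 CPM (0.125). Of cholesterol synthesis genes 2 rose and 15 fell of 22 tested (2 and 15 adjusted over the list alone). Their median was -0.51 on the log2 scale (camera adjusted p = 0.000307, adjusted p = 0.121 with an estimated correlation, 7.09e-05 to 0.121 over its alternatives), among them FDFT1 (-1.03 ± 0.056) and FDPS (-0.94 ± 0.062). Of ATF4 stress response genes 6 rose and 14 fell of 25 tested (6 and 15 adjusted over the list alone). Their median was -0.36 on the log2 scale, with the amino acid transporter SLC7A5 at -2.77 ± 0.07. That call (camera adjusted p = 0.041, adjusted p = 0.441 with an estimated correlation, 0.0295 to 0.441 over its alternatives) ended without sensitive DMSO replicate 2 (0.0517) and with a filter of 5 CPM (0.128).

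MAPK output genes moved both ways in sensitive cells with GNE-7883. The ERK phosphatase DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271) rose from 1.49 ± 0.0567 to 6.3 ± 0.641 CPM (2.07 ± 0.11) and the feedback inhibitor SPRY4 rose (1.37 ± 0.068), while the transcription factors ETV4 (-0.93 ± 0.1) and FOSL1 (-1.62 ± 0.075), the phosphatase DUSP5 (-1.62 ± 0.092) and MYC (-0.77 ± 0.056) fell. Of the MAPK pathway activity genes 3 rose and 3 fell of 10 tested (3 and 4 adjusted over the list alone). Their median was -0.04 on the log2 scale against a mean of 0.16 (camera adjusted p = 0.942). Of other ERK output genes 4 rose and 6 fell of 16 tested (4 and 6 adjusted over the list alone). Their median was -0.06 on the log2 scale (camera adjusted p = 0.645). Of BCL-2 family genes 8 rose and 6 fell of 16 tested (8 and 6 adjusted over the list alone). Their median was 0.18 on the log2 scale (camera adjusted p = 0.592), with the pro-apoptotic genes BCL2L11 (2.11 ± 0.11), BMF (1.77 ± 0.21) and BIK (1.47 ± 0.15) higher. Of cytoskeletal SRF/MRTF targets 4 rose and 9 fell of 18 tested (4 and 9 adjusted over the list alone). Their median was -0.19 on the log2 scale (camera adjusted p = 0.0528), with TAGLN at -2.18 ± 0.078 and CNN1 at -2.43 ± 0.11. That adjusted p was 0.0493 with DESeq2 size factors, 0.0488 without resistant DMSO replicate 2 and 0.0487 without resistant GNE-7883 replicate 3, and ran from 0.0487 to 0.441 over its alternatives. Of hypoxia and glycolysis genes 6 rose and 12 fell of 22 tested (6 and 12 adjusted over the list alone). Their median was -0.25 on the log2 scale (camera adjusted p = 0.0902). Markers of other cell types were mostly too low to test: 4 of 16 blood, 6 of 10 endothelial and 3 of 12 alveolar and airway markers were tested, of which 2, 2 and 1 rose and 0, 3 and 0 fell (camera adjusted p = 0.539, 0.592 and 0.539). The blood markers were CD14 (1.60 ± 0.18) and FCER1G (0.81 ± 0.31), and the call of FCER1G ended without sensitive DMSO replicates 1 (0.161) or 3 (0.057) or sensitive GNE-7883 replicates 1 (0.101) or 2 (0.0876). Over all genes 5367 rose and 5116 fell of 18035 tested (58.1%), 1487 and 1154 of them at least 2-fold. These p-values measure only the spread between these libraries, which may be technical, since the labels do not say that they came from separate cultures.

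In resistant cells the same comparison asks what GNE-7883 still does. YAP/TEAD targets fell as a list, by a median of -0.18 on the log2 scale, and interferon-stimulated genes rose. CCN2 went from 102 ± 4.27 to 69.3 ± 1.61 CPM (-0.56 ± 0.052, adjusted p = 6.19e-06, edgeR quasi-likelihood test), CCN1 from 1401 ± 27.4 to 1104 ± 14.3 CPM (-0.34 ± 0.045), and ANKRD1 (-0.73 ± 0.11), F3 (-0.62 ± 0.052) and AXL (-0.25 ± 0.05) fell. Of the YAP/TEAD targets 0 rose and 8 fell of 22 tested (0 and 13 adjusted over the list alone). Their median was -0.18 on the log2 scale (camera adjusted p = 6.4e-10, adjusted p = 0.0189 with an estimated correlation, 2.85e-11 to 0.0189 over its alternatives). The antiviral genes OAS2, from 6.97 ± 1.87 to 26.1 ± 2.23 CPM (1.92 ± 0.2), OAS1 (1.67 ± 0.23), MX2 (1.32 ± 0.18) and IFI6 (1.30 ± 0.21) were among the largest rises of genes with at least 5 CPM in a group. Of interferon-stimulated genes 24 rose and 0 fell of 27 tested (27 and 0 adjusted over the list alone). Their median was 0.79 on the log2 scale (camera adjusted p = 4.04e-26, adjusted p = 0.069 with an estimated correlation, 8.45e-34 to 0.069 over its alternatives). NDRG4 rose from 8.38 ± 0.797 to 25.4 ± 2.09 CPM, and the prostaglandin synthase gene PTGES from 19.7 ± 1.6 to 50.6 ± 0.834 CPM. KRTAP2-3, a keratin-associated protein gene with close copies, fell from 21.8 ± 1.68 to 4.62 ± 0.151 CPM (-2.24 ± 0.11), and ESM1 (-1.39 ± 0.13), MYCT1 (-1.26 ± 0.12), the activin antagonist FST (-1.26 ± 0.11), DUSP5 (-0.95 ± 0.08) and FOSL1 (-0.54 ± 0.068) fell.

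Stress, mesothelial and transport genes also moved in resistant cells. Of ATF4 stress response genes 1 rose and 16 fell of 25 tested (1 and 19 adjusted over the list alone). Their median was -0.32 on the log2 scale (camera adjusted p = 5.91e-15, adjusted p = 0.0189 with an estimated correlation, 7.62e-17 to 0.0189 over its alternatives), with STC2 at -0.93 ± 0.072, the folate enzyme MTHFD2 at -0.53 ± 0.057 and DDIT3 at -0.69 ± 0.08. Of mesothelial markers 7 rose and 0 fell of 14 tested (11 and 0 adjusted over the list alone). Their median was 0.31 on the log2 scale (camera adjusted p = 4.46e-09, adjusted p = 0.0189 with an estimated correlation, 6.62e-11 to 0.0189 over its alternatives), with CALB2, which encodes calretinin, at 0.69 ± 0.059. Of drug efflux and metabolism genes 5 rose and 0 fell of 14 tested (5 and 0 adjusted over the list alone). Their median was 0.23 on the log2 scale (camera adjusted p = 0.000215, adjusted p = 0.0189 with an estimated correlation, 5.1e-05 to 0.0189 over its alternatives), with ABCC3 at 1.26 ± 0.081. Of TGF-beta response genes 10 rose and 1 fell of 18 tested (11 and 2 adjusted over the list alone). Their median was 0.23 on the log2 scale (camera adjusted p = 0.000328, adjusted p = 0.15 with an estimated correlation, 0.00012 to 0.15 over its alternatives), with ID2 at 0.81 ± 0.079. Of G2/M genes 0 rose and 7 fell of 26 tested (0 and 12 adjusted over the list alone). Their median was -0.16 on the log2 scale (camera adjusted p = 1.63e-08, adjusted p = 0.069 with an estimated correlation, 8.93e-10 to 0.069 over its alternatives). Of S-phase genes 0 rose and 3 fell of 26 tested (0 and 3 adjusted over the list alone). Their median was -0.06 on the log2 scale. That list's call (camera adjusted p = 0.024, adjusted p = 0.155 with an estimated correlation, 0.0212 to 0.155 over its alternatives) ended without resistant DMSO replicate 3 (0.0596), without resistant GNE-7883 replicate 1 (0.0751) and with a filter of 5 CPM (0.0551). Of AP-1 genes 2 rose and 5 fell of 23 tested (2 and 8 adjusted over the list alone). Their median was -0.10 on the log2 scale. Their call (camera adjusted p = 0.0143, adjusted p = 0.392 with an estimated correlation, 0.00126 to 0.392 over its alternatives) ended without resistant DMSO replicate 2 (0.0797) and with that filter (0.185). Of fatty acid synthesis genes 1 rose and 0 fell of 12 tested (3 and 0 adjusted over the list alone). Their median was 0.09 on the log2 scale, a call (camera adjusted p = 0.024, adjusted p = 0.379 with an estimated correlation, 0.00893 to 0.379 over its alternatives) that ended without resistant GNE-7883 replicate 3 (0.053) and with that filter (0.0526).

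Of MAPK pathway activity genes in resistant cells 2 rose and 0 fell of 10 tested (2 and 2 adjusted over the list alone). Their median was 0.05 on the log2 scale (camera adjusted p = 0.701). The genes that rose were SPRY4 (0.33 ± 0.068) and DUSP6 (0.29 ± 0.078), whose call ended without resistant DMSO replicates 1 (0.0938) or 2 (0.11) or resistant GNE-7883 replicates 1 (0.087), 2 (0.0587) or 3 (0.109), each left out singly, and with limma-trend on log2 of RPKM plus 0.1 (0.0844). Of Hippo pathway components 2 rose and 1 fell of 26 tested (2 and 2 adjusted over the list alone). Their median was -0.05 on the log2 scale (camera adjusted p = 0.428). TEAD2 (0.33 ± 0.083) and WWTR1 (0.32 ± 0.077) rose and WWC1 fell (-0.17 ± 0.046), a call that ended in 9 of its 24 alternatives (adjusted p from 1.43e-05 to 0.124). The call of WWTR1 ended without resistant DMSO replicates 1 (0.0762) or 2 (0.0568) or resistant GNE-7883 replicate 3 (0.0672), over a range of 4.03e-05 to 0.0762. That of TEAD2 ended without resistant DMSO replicate 3 (0.0774) or resistant GNE-7883 replicates 1 (0.0638) or 3 (0.0758), over a range of 0.00293 to 0.0774. CCND1 (-0.03 ± 0.063), EGFR (-0.08 ± 0.13), YAP1 (-0.01 ± 0.086), TEAD1 (-0.04 ± 0.14) and TEAD4 (-0.12 ± 0.071) did not pass the test. Over all genes 947 rose and 716 fell (9.2%), 89 and 36 of them at least 2-fold, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. These counts depended on single libraries. Without sensitive DMSO replicate 2, a library of neither group compared here, 1649 rose and 1411 fell. That library enters this comparison through the fit over all 12 libraries, which share 1 estimate of the spread. All 1663 genes called with it stayed called in the same direction without it. Without resistant DMSO replicate 1 the counts were 549 and 312, without its replicate 3 they were 600 and 350, and without resistant GNE-7883 replicate 3 they were 550 and 304. Without resistant GNE-7883 replicates 1 and 2, left out singly, 342 and 457 fell. A fit on the resistant libraries alone called 1131 lower, and the correction for GC content and length called 1665 higher and 1808 lower.

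**Figure D2:**
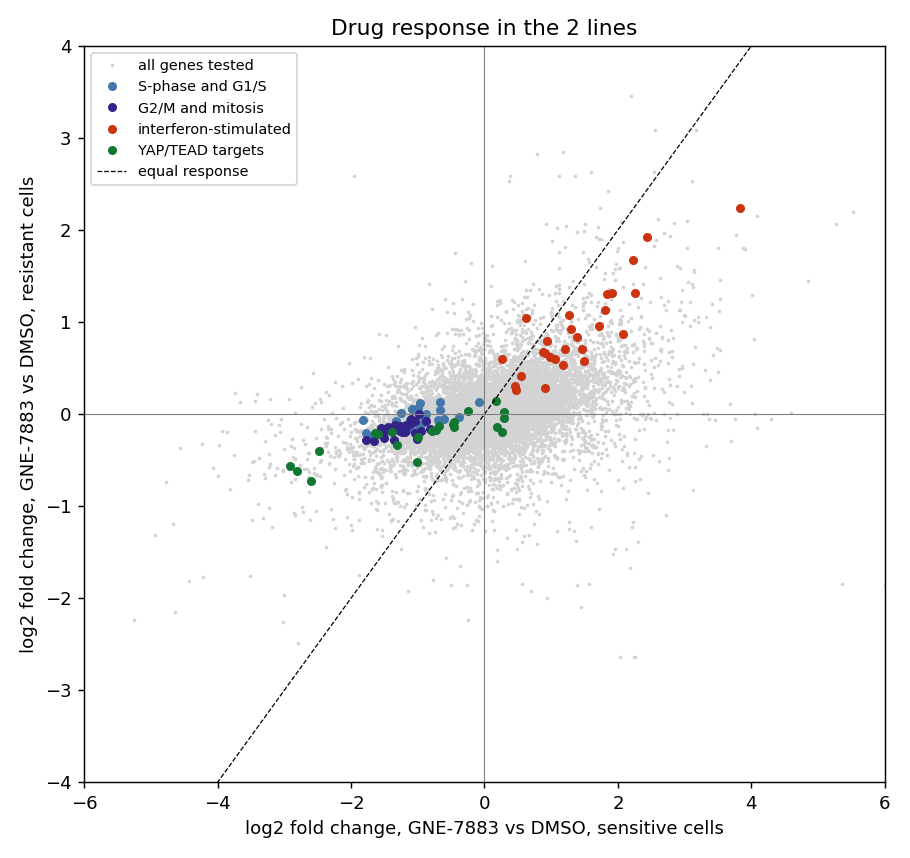
Log2 fold change with GNE-7883 against DMSO in sensitive cells (horizontal) and in resistant cells (vertical), 1 point per gene, with S-phase, G2/M, interferon-stimulated and YAP/TEAD target genes coloured and a dashed line of equal response. The median of G2/M genes is -1.21 in sensitive and -0.16 in resistant cells, and that of interferon-stimulated genes is 1.26 and 0.79, with 7 points outside the axes.

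The comparison of resistant with sensitive cells in DMSO asks how the derived line differs without the drug. MAPK output genes were higher. DUSP6 was 1.49 ± 0.0567 CPM in sensitive and 18.2 ± 1.47 CPM in resistant cells (3.60 ± 0.1, adjusted p = 2.1e-13, edgeR quasi-likelihood test). ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620) was at 10.6 ± 0.312 and 39 ± 3.57 CPM (1.89 ± 0.088), and FOSL1 at 49.2 ± 3 and 184 ± 3.49 CPM (1.90 ± 0.071). DUSP4 (2.21 ± 0.066), ETV5 (1.73 ± 0.057) and PHLDA1 (1.70 ± 0.059) were also higher, while SPRY4 (0.16 ± 0.069) and CCND1 (0.11 ± 0.063) did not pass the test. Of MAPK pathway activity genes 8 were higher and 0 lower of 10 tested (9 and 0 adjusted over the list alone). Their median was 1.64 on the log2 scale (camera adjusted p = 8.69e-07, adjusted p = 0.0442 with an estimated correlation, 2.15e-07 to 0.0442 over its alternatives). Of other ERK output genes 13 were higher and 1 lower of 16 tested (15 and 1 adjusted over the list alone). Their median was 0.85 on the log2 scale (camera adjusted p = 8.69e-07, adjusted p = 0.0178 with an estimated correlation, 1.99e-07 to 0.0178 over its alternatives), with the chromatin protein gene HMGA2 (ENSG00000149948, chromosome 12, 65824131 to 65966295) at 2.21 ± 0.306 and 77.9 ± 3.32 CPM (5.13 ± 0.087) and the cytokine LIF at 0.95 ± 0.055. Of AP-1 genes 12 were higher and 2 lower of 23 tested (12 and 2 adjusted over the list alone). Their median was 0.22 on the log2 scale (camera adjusted p = 0.00579, adjusted p = 0.354 with an estimated correlation, 0.00189 to 0.354 over its alternatives). EGFR was higher (1.21 ± 0.13). Of receptor tyrosine kinases 7 were higher and 12 lower of 27 tested (7 and 13 adjusted over the list alone). Their median was -0.14 on the log2 scale (camera adjusted p = 0.0619). IGF1R (-2.51 ± 0.098), PDGFRB (-2.26 ± 0.071) and ERBB3 (-1.19 ± 0.07) were lower. The list's adjusted p ran from 0.022 to 0.633 over its alternatives. It was 0.027 without sensitive DMSO replicate 2, 0.0489 without resistant DMSO replicate 2 and 0.022 with a filter of 5 CPM. Of RAS-MAPK components 11 were higher and 7 lower of 28 tested (11 and 7 adjusted over the list alone). Their median was 0.07 on the log2 scale (camera adjusted p = 0.843), with HRAS at -0.16 ± 0.098, not past the test.

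YAP/TEAD targets went both ways between the lines in DMSO: 11 were higher and 9 lower of 22 tested (11 and 9 adjusted over the list alone). Their median was 0.12 on the log2 scale and their mean -0.01 (camera adjusted p = 0.726). CCN2 (0.67 ± 0.053), CCN1 (0.47 ± 0.045), AMOTL2 (0.66 ± 0.067) and GADD45A (1.06 ± 0.064) were higher in resistant cells, and ANKRD1 (-1.38 ± 0.1), IGFBP3 (-1.19 ± 0.049) and CCDC80 (-0.93 ± 0.044) lower. AXL did not pass the test (0.06 ± 0.05). TEAD4 was lower (-0.81 ± 0.071), WWTR1 lower (-0.30 ± 0.077) and YAP1 higher (0.33 ± 0.086), with TEAD1 (-0.21 ± 0.14) and TEAD3 (0.10 ± 0.064) not past the test. The values of TEAD1 and YAP1 lean on sensitive DMSO replicate 2, which stood apart. TEAD1 was at 518.9, 305.2 and 547.4 CPM in sensitive and 386.2, 375.1 and 424.2 CPM in resistant DMSO replicates 1 to 3. YAP1 was at 222.4, 166.6 and 225.8 CPM in sensitive and 253.2, 248 and 269 CPM in resistant ones. The activin subunit INHBA was at 18.9 ± 1.62 and 287 ± 3.62 CPM (3.92 ± 0.064), and the efflux pump ABCG2 (ENSG00000118777, chromosome 4, 88090264 to 88231322) at 8.47 ± 1.02 and 150 ± 6.76 CPM (4.14 ± 0.097). ITGBL1 (ENSG00000198542, chromosome 13, 101452593 to 101720856) had 2653 counts in the resistant and 4 in the sensitive libraries, a ratio of 696 (95% counting interval 272 to 2560). SLC8A1 (4.46 ± 0.13), CROT (4.42 ± 0.18), MYCT1 (4.37 ± 0.17) and ADAMTS6 (3.97 ± 0.12) followed. CYP17A1, an enzyme of steroid synthesis (ENSG00000148795, chromosome 10, 102830531 to 102837533), was at 103 ± 3.43 CPM in sensitive and 0.256 ± 0.097 CPM in resistant cells (-8.70 ± 0.11). CYTL1 had 643 counts in the sensitive and 0 in the resistant libraries, 204-fold lower against a floor of 3 counts over the group (lower 95% counting limit of the ratio 166). The surfactant protein gene SFTPD (-7.30 ± 0.15), CLSTN2 (-6.13 ± 0.18) and the acute phase genes SAA1 (-5.85 ± 0.14) and SAA2 (-5.51 ± 0.13), near-identical copies, were also lower.

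Differentiation markers differed between the lines as well. Of mesothelial markers 1 was higher and 11 lower of 14 tested (1 and 11 adjusted over the list alone). Their median was -0.61 on the log2 scale (camera adjusted p = 1.08e-05, adjusted p = 0.0469 with an estimated correlation, 2.68e-06 to 0.0469 over its alternatives), with CALB2 at -2.02 ± 0.061 and ITLN1 at -2.26 ± 0.12. Of epithelial markers 2 were higher and 8 lower of 10 tested (2 and 8 adjusted over the list alone). Their median was -0.81 on the log2 scale (camera adjusted p = 0.00266, adjusted p = 0.0469 with an estimated correlation, 0.000564 to 0.0469 over its alternatives), with CDH1, which encodes E-cadherin, at -3.99 ± 0.28 and KRT18 at -1.19 ± 0.081. Of mesenchymal markers 9 were higher and 6 lower of 20 tested (10 and 7 adjusted over the list alone). Their median was 0.20 on the log2 scale (camera adjusted p = 0.348), with the transcription factor SNAI2 (3.64 ± 0.11) and VIM (1.28 ± 0.068) higher and COL3A1 lower (-4.62 ± 0.22). Of squamous markers 2 were higher and 4 lower of 9 tested (3 and 5 adjusted over the list alone). Their median was -0.52 on the log2 scale (camera adjusted p = 0.829). Of growth factor ligands 13 were higher and 6 lower of 24 tested (13 and 6 adjusted over the list alone). Their median was 0.57 on the log2 scale (camera adjusted p = 0.12), with FGF5 (2.12 ± 0.093), VEGFC (1.80 ± 0.092) and NRG1 (1.67 ± 0.084) higher and FGF18 lower (-3.90 ± 0.08). Of p53 targets 16 were higher and 0 lower of 19 tested (16 and 0 adjusted over the list alone). Their median was 0.46 on the log2 scale (camera adjusted p = 8.53e-06, adjusted p = 0.0178 with an estimated correlation, 5.78e-07 to 0.0178 over its alternatives), with FAS at 0.62 ± 0.061. Of ATF4 stress response genes 18 were higher and 5 lower of 25 tested (18 and 5 adjusted over the list alone). Their median was 0.53 on the log2 scale (camera adjusted p = 0.000227, adjusted p = 0.188 with an estimated correlation, 2.56e-05 to 0.188 over its alternatives), with the serine synthesis enzyme PSAT1 at 1.38 ± 0.065. Of cholesterol synthesis genes 1 was higher and 16 lower of 22 tested (1 and 16 adjusted over the list alone). Their median was -0.32 on the log2 scale (camera adjusted p = 0.000104, adjusted p = 0.0589 with an estimated correlation, 3.69e-05 to 0.0589 over its alternatives). Of fatty acid synthesis genes 0 were higher and 10 lower of 12 tested (0 and 11 adjusted over the list alone). Their median was -0.37 on the log2 scale (camera adjusted p = 0.000956, adjusted p = 0.188 with an estimated correlation, 6.36e-05 to 0.188 over its alternatives), with the desaturase FADS2 at -0.83 ± 0.057. Of Wnt and Notch targets 5 were higher and 5 lower of 17 tested (5 and 5 adjusted over the list alone). Their median was 0.05 on the log2 scale (camera adjusted p = 0.822). S-phase (0.02), G2/M (0.06) and interferon (-0.01, mean 0.02) lists had medians near 0 and were not called (camera adjusted p = 0.396, 0.475 and 0.796). Over all genes 4367 were higher and 4408 lower in resistant cells (48.7%), 787 and 1345 of them at least 2-fold, and only 1 resistant line was profiled.

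**Figure D3:**
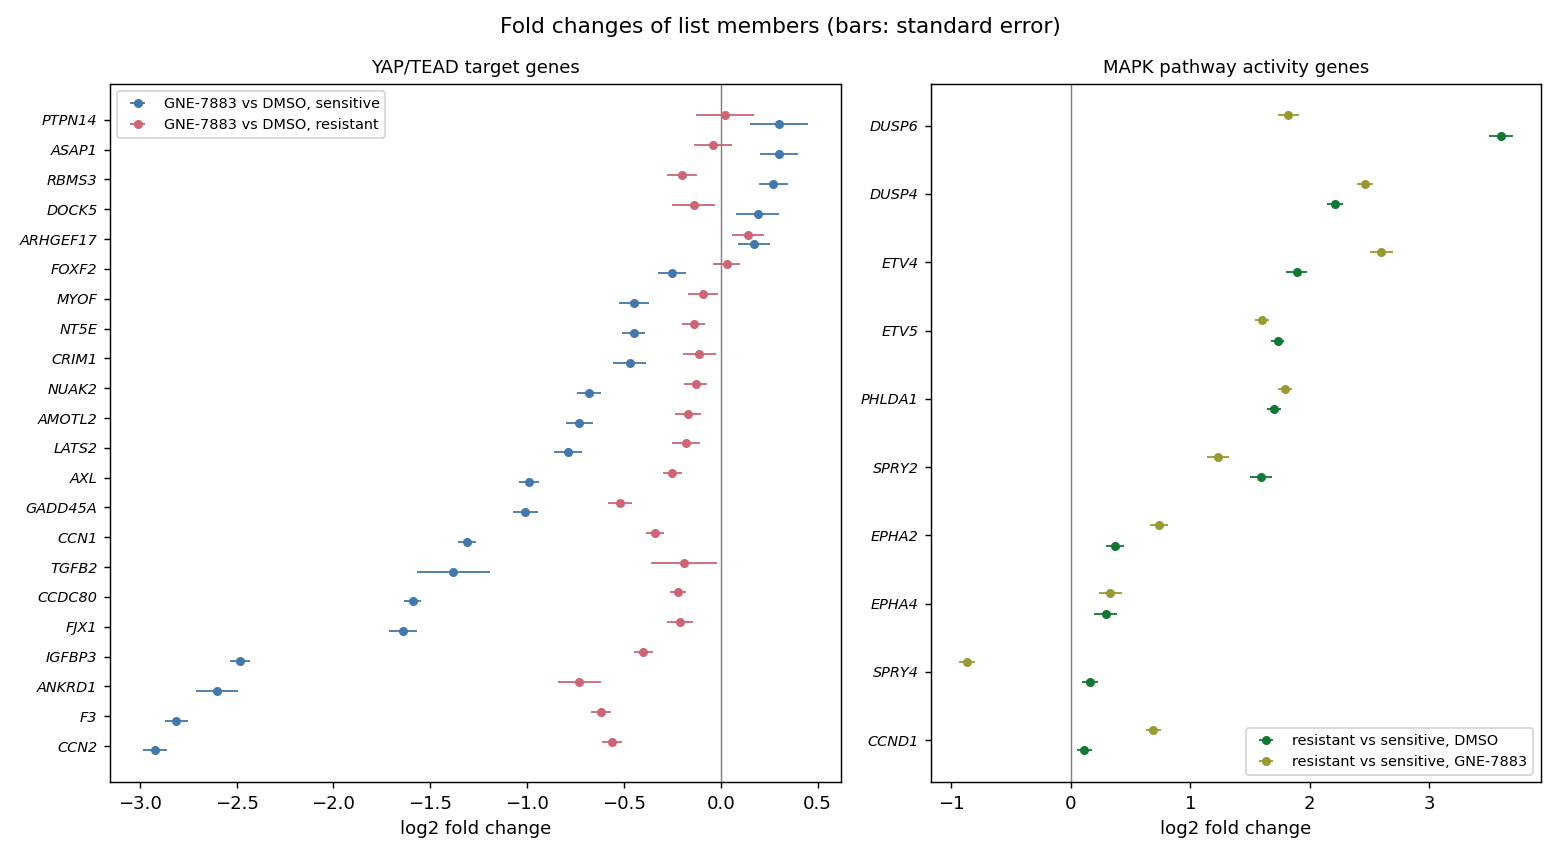
Log2 fold change with its standard error of each YAP/TEAD target (left, GNE-7883 against DMSO in sensitive and in resistant cells) and each MAPK pathway activity gene (right, resistant against sensitive cells in DMSO and in GNE-7883). The medians on the left are -0.76 and -0.18, and on the right 1.64 and 1.42.

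The comparison of the lines with GNE-7883 present asks how they differ under the drug. YAP/TEAD targets, cell cycle genes and MAPK output genes were higher in resistant cells. CCN2 was at 8.49 ± 0.299 CPM in sensitive and 69.3 ± 1.61 CPM in resistant cells (3.03 ± 0.061, adjusted p = 1.97e-15, edgeR quasi-likelihood test), and F3 (1.93 ± 0.056), THBS1 (3.83 ± 0.12), CCN1 (1.43 ± 0.046) and AXL (0.80 ± 0.051) were higher in resistant cells. Of YAP/TEAD targets 17 were higher and 3 lower of 22 tested (17 and 3 adjusted over the list alone). Their median was 0.72 on the log2 scale (camera adjusted p = 2.8e-05, adjusted p = 0.0776 with an estimated correlation, 1.22e-05 to 0.0776 over its alternatives). Of S-phase genes 25 were higher and 0 lower of 26 tested (25 and 0 adjusted over the list alone). Their median was 1.11 on the log2 scale (camera adjusted p = 3.8e-12, adjusted p = 0.00434 with an estimated correlation, 1.23e-12 to 0.00434 over its alternatives). Of G2/M genes 26 were higher and 0 lower of 26 tested (26 and 0 adjusted over the list alone). Their median was 1.12 on the log2 scale (camera adjusted p = 2.18e-14, adjusted p = 0.0413 with an estimated correlation, 6.56e-15 to 0.0413 over its alternatives). FOSL1 (2.97 ± 0.076), ETV4 (2.60 ± 0.096), DUSP4 (2.46 ± 0.068), DUSP6 (1.82 ± 0.086), ETV5 (1.60 ± 0.057), CCND1 (0.69 ± 0.063) and MYC (0.67 ± 0.055) were higher, and SPRY4 lower (-0.87 ± 0.067). Of MAPK pathway activity genes 9 were higher and 1 lower of 10 tested (9 and 1 adjusted over the list alone). Their median was 1.42 on the log2 scale (camera adjusted p = 8.54e-05, adjusted p = 0.0882 with an estimated correlation, 5.14e-05 to 0.0882 over its alternatives). Of other ERK output genes 13 were higher and 1 lower of 16 tested (13 and 1 adjusted over the list alone). Their median was 0.77 on the log2 scale (camera adjusted p = 5.23e-05, adjusted p = 0.0413 with an estimated correlation, 3e-05 to 0.0413 over its alternatives). ADAMTS6 (6.98 ± 0.19), RGS4, a regulator of G-protein signalling (5.75 ± 0.13), INHBA (5.18 ± 0.07), HMGA2 (5.09 ± 0.089) and ABCG2 (4.61 ± 0.1) were among the farthest above, with ITGBL1 (6.91 ± 0.22). The folds of ADAMTS6 and ITGBL1 rest on few counts, 15 and 16 over the 3 sensitive GNE-7883 libraries.

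HP (-9.96 ± 0.24), CYP17A1 (-10.38 ± 0.11) and SFTPD (-8.91 ± 0.14) were far lower in resistant cells with GNE-7883. The fold of HP rests on 10 counts over the resistant libraries, against 8624 over the sensitive ones. MUC16 had 4206 counts in the sensitive and 3 in the resistant libraries, a ratio of 1590 (95% counting interval 544 to 7710). CYTL1 had 820 and 0, 310-fold lower against that floor (lower 95% counting limit of the ratio 251). Of mesothelial markers 1 was higher and 11 lower of 14 tested (1 and 11 adjusted over the list alone). Their median was -0.62 on the log2 scale (camera adjusted p = 0.000272, adjusted p = 0.0882 with an estimated correlation, 8.22e-05 to 0.0882 over its alternatives). Of NF-kB cytokine genes 2 were higher and 17 lower of 21 tested (2 and 17 adjusted over the list alone). Their median was -1.55 on the log2 scale (camera adjusted p = 2.8e-05, adjusted p = 0.185 with an estimated correlation, 6.07e-06 to 0.185 over its alternatives), with CCL2 at -2.07 ± 0.068 and IL1B, in the other direction, at 2.32 ± 0.07. Of NRF2 targets 2 were higher and 11 lower of 18 tested (2 and 11 adjusted over the list alone). Their median was -0.65 on the log2 scale (camera adjusted p = 0.00451, adjusted p = 0.147 with an estimated correlation, 0.00294 to 0.147 over its alternatives). Of BCL-2 family genes 8 were higher and 5 lower of 16 tested (8 and 5 adjusted over the list alone). Their median was 0.26 on the log2 scale against a mean of -0.29 (camera adjusted p = 0.811), with BCL2L11 (-2.86 ± 0.12) and BIK (-2.54 ± 0.16) lower and BCL2 higher (2.38 ± 0.2). Of interferon-stimulated genes 4 were higher and 15 lower of 27 tested (4 and 16 adjusted over the list alone). Their median was -0.48 on the log2 scale. Their call (camera adjusted p = 0.0464, adjusted p = 0.688 with an estimated correlation, 0.00692 to 0.688 over its alternatives) ended without sensitive GNE-7883 replicate 2 (0.1) or resistant GNE-7883 replicates 1 (0.0578) or 2 (0.0583). Of ATF4 stress response genes 15 were higher and 8 lower of 25 tested (16 and 8 adjusted over the list alone). Their median was 0.70 on the log2 scale, a call (camera adjusted p = 0.0447, adjusted p = 0.433 with an estimated correlation, 0.0324 to 0.433 over its alternatives) that ended without resistant GNE-7883 replicate 1 (0.0541) and with a filter of 5 CPM (0.142). Over all genes 5544 were higher and 5615 lower (61.9%), 1503 and 2087 of them at least 2-fold.

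The difference of the 2 responses asks where GNE-7883 acts differently in the resistant line. A positive value means a response that is higher in resistant cells. CCN2 responded by -2.92 ± 0.061 in sensitive and -0.56 ± 0.052 in resistant cells, a difference of 2.36 ± 0.08 (adjusted p = 2.98e-11, edgeR quasi-likelihood test). The differences of ANKRD1 (1.86 ± 0.16), IGFBP3 (2.08 ± 0.07), F3 (2.18 ± 0.076), CCN1 (0.97 ± 0.063), AXL (0.74 ± 0.071) and AMOTL2 (0.57 ± 0.095) were also positive. Of YAP/TEAD targets 17 had a higher and 1 a lower response of 22 tested (17 and 2 adjusted over the list alone), with a median difference of 0.56 (camera adjusted p = 6.99e-08, adjusted p = 0.0314 with an estimated correlation, 9.6e-10 to 0.0314 over its alternatives). All 26 S-phase and all 26 G2/M genes had a higher response, with median differences of 1 and 1.05 (camera adjusted p = 3.36e-19 and 2.1e-22, or adjusted p = 0.000784 and 0.0105 with an estimated correlation, 9.06e-20 to 0.000784 and 4.06e-25 to 0.0105 over their alternatives). NPPB (3.91 ± 0.14), RGS7 (4.03 ± 0.38), THBS1 (2.97 ± 0.15) and MGLL (2.66 ± 0.096) were among the most positive differences of genes with at least 5 CPM in a group, with KRT4 (3.26 ± 0.22) and ANKRD2 (3.17 ± 0.22), which were under 2 CPM in resistant cells in DMSO. PRG4 (-4.57 ± 0.36), MAP1A (-4.24 ± 0.47) and ANGPTL7 (-4 ± 0.52) were the most negative among called genes of that level, clones, pseudogenes and antisense names left out. Each was under 0.5 CPM in resistant cells in DMSO. ESM1 rose in sensitive cells and fell by 1.39 on the log2 scale in resistant cells, a difference of -3.70 ± 0.23.

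Among MAPK pathway activity genes the differences went both ways, with DUSP6 (-1.78 ± 0.14) and SPRY4 (-1.03 ± 0.096) negative and ETV4 (0.71 ± 0.13) and CCND1 (0.58 ± 0.089) positive. In that list 4 had a higher and 3 a lower response of 10 tested (4 and 3 adjusted over the list alone), with a median of 0.06 and a mean of -0.13 (camera adjusted p = 0.885). Of NF-kB cytokine genes 0 had a higher and 15 a lower response of 21 tested (0 and 16 adjusted over the list alone), with a median of -0.96 (camera adjusted p = 1.69e-08, adjusted p = 0.0929 with an estimated correlation, 9.53e-10 to 0.0929 over its alternatives). Of interferon-stimulated genes 0 had a higher and 12 a lower response of 27 tested (0 and 12 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.00111, adjusted p = 0.657 with an estimated correlation, 3.99e-06 to 0.657 over its alternatives). Of cholesterol synthesis genes 14 had a higher and 0 a lower response of 22 tested (15 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 6.1e-06, adjusted p = 0.0448 with an estimated correlation, 7.4e-07 to 0.0448 over its alternatives). The response of BCL2L11 was lower (-2.10 ± 0.17). Over all genes 3435 had a higher and 3008 a lower response (35.7%), 753 and 741 of them by at least 2-fold. With the GC and length correction 4621 had a lower response.

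Across genes, which are not independent replicates, the responses to GNE-7883 in the lines had Pearson's r 0.456 and Spearman's rho 0.48. Simulations in which no gene changed in either line gave r -0.007. These responses share no libraries, so that small value was fixed by the design. It is not a baseline for the real r, and nothing is concluded from it. Both lines called 799 genes higher and 617 lower, where independence gives 281.8 and 203.1, and 98 genes were called in opposite directions with the difference also called. Pearson's r was 0.076 without a filter on low counts and 0.109 with DESeq2, which was also run without that filter. The response in sensitive cells and the difference between the lines in DMSO share the sensitive DMSO libraries, so that part of any excess may come from them. Their r across genes was -0.096 (rho -0.044) and their covariance -0.0654. Simulations in which no gene changed gave r 0.485 and a covariance of 0.0253 from the shared libraries. With no real changes in it, that simulated r is not the value to expect here, and only the covariances can be compared. Without the filter the r of the real data was positive, 0.29 in edgeR and 0.222 in DESeq2. The differences between the lines in DMSO and in GNE-7883 had r 0.77 and rho 0.622 across genes, with 3053 genes higher and 3112 lower in both.

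**Figure D4:**
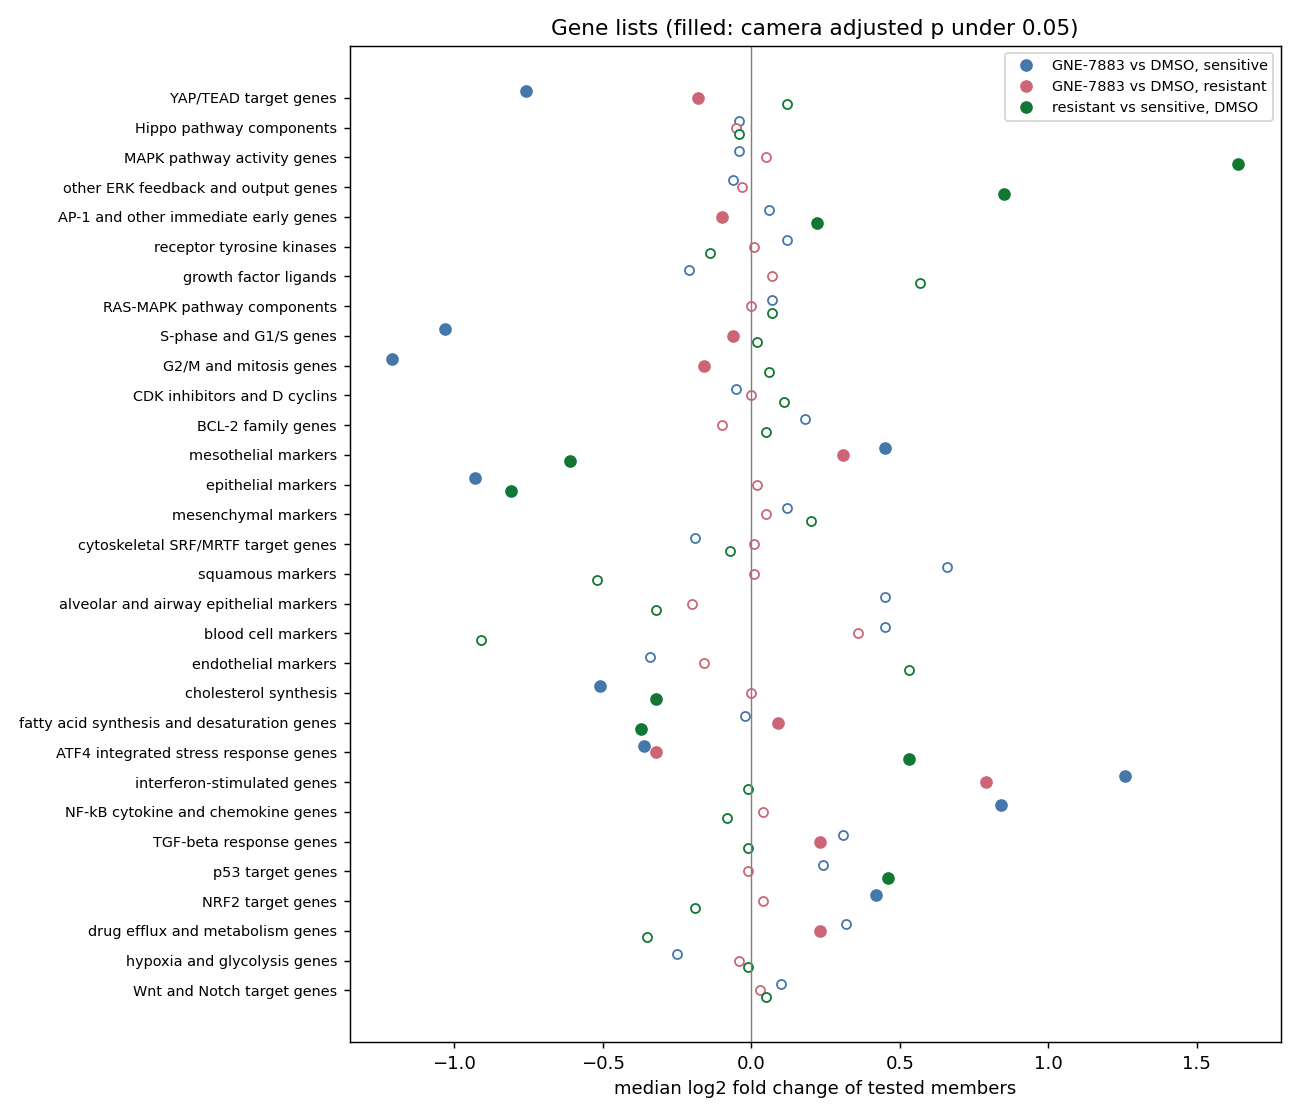
Median log2 fold change of the 31 gene lists for GNE-7883 against DMSO in sensitive cells, the same in resistant cells, and resistant against sensitive cells in DMSO, with filled points where the camera adjusted p was under 0.05. The G2/M median is -1.21, -0.16 and 0.06 in these comparisons.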

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

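The tests of library depth, of a common scaling, of precision and of genes already at their treated level were chosen only after the results were seen.

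The response to GNE-7883 differed between the lines by the test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg), with 3435 genes having a higher and 3008 a lower response in resistant cells. By camera, positive median differences were found for YAP/TEAD targets (0.56), S-phase genes (1), G2/M genes (1.05), epithelial markers (0.85), cytoskeletal SRF/MRTF targets (0.21) and cholesterol synthesis genes (0.51). Negative ones were found for interferon-stimulated genes (-0.51), NF-kB cytokine genes (-0.96), p53 targets (-0.24) and NRF2 targets (-0.36). With an estimated correlation the adjusted p was 0.082 for epithelial markers (0.00336 to 0.082 over the alternatives), 0.411 for SRF/MRTF targets (0.00794 to 0.411), 0.657 for interferon-stimulated genes (3.99e-06 to 0.657), 0.0929 for NF-kB genes (9.53e-10 to 0.0929), 0.0929 for p53 targets (0.00716 to 0.0929) and 0.0929 for NRF2 targets (0.001 to 0.0929). The p53 call also ended without resistant DMSO replicate 2 (0.0887) or resistant GNE-7883 replicate 3 (0.0528), and a filter of 5 CPM ended those of epithelial markers (0.0744) and SRF/MRTF targets (0.0993).

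Among called genes of at least 5 CPM in a group, clones, pseudogenes and antisense genes left out, the most positive differences of log2 fold change were those of RGS7 (4.03), NPPB (3.91), KRT4 (3.26), ANKRD2 (3.17), KRTAP2-3 (3.02), ADAMTS6 (3.01), THBS1 (2.97), FRMPD3 (2.94), FGF1 (2.91) and MGLL (2.66). The most negative among them were those of PRG4 (-4.57), MAP1A (-4.24), ANGPTL7 (-4), ESM1 (-3.7), ENPP2 (-2.93), AQP1 (-2.83), EPB42 (-2.83), HSD17B6 (-2.79), PDGFRA (-2.58) and TNIP3 (-2.52). Of the pathway genes, CCN2 (2.36), ANKRD1 (1.86), FOSL1 (1.08), CCN1 (0.97), TEAD4 (0.88), HRAS (0.77), AXL (0.74), ETV4 (0.71), CCND1 (0.58), AMOTL2 (0.57), MYC (0.55) and TEAD3 (0.4) differed upward. DUSP6 (-1.78), SPRY4 (-1.03), EGFR (-0.61), YAP1 (-0.49), WWTR1 (-0.49) and TEAD2 (-0.48) differed downward. The call of EPB42 ended without resistant DMSO replicate 1 (-2.24, adjusted p 0.146, edgeR). With limma-trend on log2 of RPKM plus 1, the difference of ADAMTS6 was called in the other direction (-0.3, adjusted p 0.00963, 2.45e-22 to 0.00963 over the alternatives) and the call of KRTAP2-3 ended (0.16, adjusted p 0.408, 7.9e-17 to 0.408). The call of EGFR ended without sensitive GNE-7883 replicate 1 (0.0511), resistant DMSO replicate 3 (0.0811) or resistant GNE-7883 replicates 1 (0.0502), 2 (0.0559) or 3 (0.0602).

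For the 4 comparisons of 2 groups there are 10 splits of the 6 libraries each, too few for a share under 0.05: 1 of the 10, the real one, gave as many called genes, with real counts of 10483, 1663, 8775 and 11159 and a highest other count of 0. For the difference of the responses, 4 of 55 splits drawn from 200 possible ones, the real one included, gave as many genes as the real 6443, with 7713 in the highest other. This test cannot decide on chance, since a split that keeps both sensitive groups whole also keeps the sensitive response. The 4 other splits that kept both sensitive groups whole gave 6331 to 7713 genes, 3 of them as many as the real split, and the other 50 gave 0, so that these counts follow the structure of the sensitive groups.

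The smaller response of resistant cells was weighed first. A single scaling of every gene's response would give equal slopes of resistant on sensitive fold changes. The slopes were 0.629 ± 0.03 for 27 interferon-stimulated and 0.106 ± 0.01 for 52 cell cycle genes (standard error across genes), a difference of 0.523 ± 0.032. Those errors treat the genes of a list as independent, which they are not, and leave out the spread between libraries. The slopes therefore argue against a single scaling only by their size, and for these lists. Of 1895 genes called at least 2-fold in sensitive cells and with a smaller response in resistant cells, 25.5% (exact 95% interval 23.5 to 27.5) were called in the drug's direction in resistant DMSO cells, at any size, and 34.4% in the opposite direction, which argues against a level already reached without drug as the whole cause in these genes and leaves it open for the former. For lower precision each line was fitted alone. The median standard error over 1771 of these genes in the resistant line was 0.798 times that in the sensitive one (bootstrap 95% interval 0.766 to 0.83). It was 1.02 to 1.09 times (highest limit 1.12, below the bound of 1.5) without sensitive DMSO replicate 2 and 1 resistant DMSO library. These genes were picked by a called difference of responses, so the ratio cannot decide on precision as a cause. In the fit that made the calls, the median standard error over all 18035 genes was 0.107 for the drug in sensitive and 0.105 in resistant cells. The median size of the log2 fold change was 0.395 and 0.131. Those values argue against lower precision in that fit as the cause of the smaller number of calls. That fit shares 1 estimate of the spread, so its errors do not measure the precision of each line. A response altered with the acquired resistance may underlie the difference, a hypothesis from 1 resistant line that no test here decides.

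Interferon-stimulated genes were higher with GNE-7883 in both lines by camera (adjusted p = 0.256 in sensitive and 0.069 in resistant cells with an estimated correlation, 7.33e-13 to 0.256 and 8.45e-34 to 0.069 over the alternatives). GC content and length bias as the whole cause was argued against, since 24 of the 24 members called in resistant cells stayed called after the trend was removed. Blood cells as a source were argued against, since their markers rose by 0.442% of the rise of interferon genes in sensitive cells and by 0.0808% in resistant cells. A response of both lines to the drug may underlie the rise, as a hypothesis, and its dose and time are not given.

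Sensitive DMSO replicate 2 stood apart from the other two of its group. Its deviations had 2.35 times the median SD of the other 11 libraries, and 1.89 times after the GC and length trend was removed, above the bound of 1.5 set for that trend as the whole cause. Lower depth was argued against by its 42.8 M counts, between 37.7 and 44.7 M in the others. What set it apart stays open, and no biological explanation was tested.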

How the results depend on the processing

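The correction for GC content and length, alone and with the replicate block, was tried only after the data were seen. The test against a 1.5-fold change (glmTreat) called 1666 genes higher and 1521 lower for GNE-7883 in sensitive cells, 49 and 11 in resistant cells, 897 and 1404 between the lines in DMSO, 2043 and 2370 in GNE-7883, and 812 and 538 for the difference of responses, by its construction. For GNE-7883 in resistant cells, the correction called 1665 higher and 1808 lower, with the block 1618 and 1779, and the fit on 2 groups called 1131 lower. For the difference of responses the correction called 4621 lower, and 4606 with the block. The cause was not tested. Leaving out 1 library gave 549 to 1649 higher and 304 to 1411 lower for GNE-7883 in resistant cells, 4902 to 5463 and 4594 to 5497 in sensitive cells, 3715 to 4633 and 3954 to 4489 between the lines in DMSO, 5222 to 6093 and 4989 to 6088 in GNE-7883, and 3108 to 3788 and 2232 to 3323 for the difference. Lists are counted here for GNE-7883 in sensitive cells, in resistant cells, the lines in DMSO, the lines in GNE-7883 and the difference of responses. In that order camera called 10, 10, 9, 10 and 10 lists and an estimated correlation left 3, 4, 5, 3 and 4. In the same order fry, which asks another question, called 27, 13, 24, 28 and 16. Between the lines in GNE-7883 the medians of YAP/TEAD targets (0.72) and MAPK activity genes (1.42) were not called with an estimated correlation (adjusted p 0.0776 and 0.0882). Signs of fry's call opposed camera's for MAPK activity genes in sensitive cells (median -0.04), BCL-2 family (0.26) and Wnt and Notch genes (-0.01) between the lines in GNE-7883, and TGF-beta genes (-0.01) in DMSO, where members go both ways. The correlation of the responses was 0.657 with 5 CPM and, without a filter, 0.076 in edgeR and 0.109 in DESeq2. That of the sensitive response with the difference in DMSO was, without a filter, 0.29 in edgeR and 0.222 in DESeq2, against -0.096. With 1 RPKM added before logs, which shrinks folds of low genes, the called difference of responses turned for ADAMTS6 (-0.3), and the calls of ROBO4 (-0.01) and KRTAP2-3 (0.16) ended. Of the other settings of named genes, 16723 kept direction and side of the threshold, 382 lost the call, 83 gained it and 2 turned, and for lists 2612, 49, 76 and 3. Depth limits genes under about 0.0941 CPM.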

Other observations

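The test of genome windows was chosen only after the results were seen.

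Some genes of drug transport and survival stood out between the lines. ABCG2, an efflux pump, was at 8.47 ± 1.02 CPM in sensitive and 150 ± 6.76 CPM in resistant cells in DMSO, while ABCC3 (-1.39 ± 0.081), the sulfotransferase SULT1A1 (-1.90 ± 0.065) and ALDH1A3 (-0.84 ± 0.045) were lower, and of the drug efflux and metabolism list 5 were higher and 8 lower of 14 tested (5 and 8 adjusted over the list alone, camera adjusted p = 0.278, 0.0356 with a filter of 5 CPM, 0.0356 to 0.354 over its alternatives). The hypoxia gene CA9 was lower (-2.70 ± 0.1) and the glucose transporter SLC2A1 higher (1.05 ± 0.055) in resistant cells, and of hypoxia and glycolysis genes 7 were higher and 8 lower of 22 tested (7 and 8 adjusted over the list alone, camera adjusted p = 0.829). The Wnt antagonist DKK1 was higher (1.82 ± 0.056) and the Wnt target AXIN2 lower (-1.63 ± 0.15). In sensitive cells with GNE-7883 the Notch target HEY1 rose (2.32 ± 0.24), as did the receptor gene PDGFRA (3.13 ± 0.14) and the ligand gene PDGFD (2.11 ± 0.081), while the receptor gene ERBB3 fell (-2.52 ± 0.074). The anti-apoptotic gene BCL2 was higher in resistant cells in DMSO (1.54 ± 0.16), as was MCL1 (0.54 ± 0.05), while of BCL-2 family genes 6 were higher and 4 lower of 16 tested (6 and 4 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.505).

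Genes that lie together on a chromosome differed together between the lines in 10 of 258 windows of 10 Mb with at least 15 of the 10829 genes used. In such a window at least 80% of the genes had 1 sign in DMSO. The median log2 fold change was at least 0.3 in size, with the same sign, in both media. Counts of genes by sign below are those in DMSO. Of the 10, 8 were higher and 2 lower in resistant cells. With genes shuffled over positions 1000 times, 0.034 windows were found on average and 2 at most. Of the 10 windows, 7 still met these limits after the GC and length correction. On chromosome 22, from 20 to 30 Mb, 50 of 57 genes were higher, with a median of 0.41 in DMSO and 0.54 in GNE-7883, and from 30 to 40 Mb 71 of 85, with 0.36 and 0.48. On chromosome 10, from 10 to 20 Mb, 29 of 35 genes were higher, with 0.53 and 0.77. On chromosome 18, from 40 to 50 Mb, 15 of 18 genes were lower, with -0.48 and -0.49. DNA copy number was not analysed here.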
